A study of Mus musculus with 9 samples.

How the data were processed

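RNA from 3 mouse ES cell lines (wild type, PKM1 knock-in, PKM2 knock-in) at days 0, 3 and 7 was measured on 9 one-colour Agilent arrays, 1 per line and day. Per the labels, total RNA was purified on RNeasy columns and 0.1 µg was labelled with Cy3 by the Low Input Quick Amp method. The intensity values were made by the authors with Agilent Feature Extraction 10.10, per the file headers and processing notes, which subtracts background and gives a processed signal per spot. The deposited value table holds the same intensity values rounded to 3 significant digits (largest difference 0.497 percent). Growth conditions beyond LIF and the use of feeder cells are not given in the sources used here.

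Each array held 62976 spots, of which 3671 were controls and were left out. Between 133 and 225 spots per array carried a quality flag. Probes were named through the RefSeq accession of the array annotation and the supplied table of accessions and symbols. Of 55681 probes, 27235 received 1 symbol and 28446 none, and 16194 carried the name of a chromosome region. This left 20660 named genes, 5476 of them with several probes. Probes without a symbol were not analysed here.

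Processed signals were scaled so that the 75th percentile of each array was equal, floored at 5 and log2 transformed. Probes well above background on at least 3 of 9 arrays were kept, and the probe with the highest mean signal stood for a gene, which gave 15011 genes. An additive model of genotype and day was fitted to all 9 arrays in limma 3.58.1 (R 4.3.3, version 1.17.8 of the data.table package) with empirical Bayes moderation. The 6 contrasts between days and between genotypes and F tests over days and over genotypes were adjusted by the Benjamini and Hochberg method, each over all genes tested, and an adjusted p under 0.05 was called. Standard errors are those of the moderated fit. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.

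Before the data were examined, 42 gene lists were fixed for pluripotency states, germ layers, extraembryonic tissues, metabolism, signalling and stress. The 40 with at least 3 members tested were tested with camera at a preset correlation of 0.01. The Y-linked and X inactivation lists had too few members and are reported by gene. Camera with a correlation estimated from the residuals and fry were run beside it. Members were also adjusted over the list alone. Differences between single arrays were given no p-value. List medians were placed among 10000 random lists matched in 20 expression bins (seed 1), and those below the 2.5 or above the 97.5 percentile were counted.

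The genes named were set by a rule fixed beforehand. Every probe of Pkm and Pklr, Xist and the Y-linked genes were read on every array. For each list described, up to 4 called members with the largest change were named, or up to 2 where none was called. For each contrast the 10 largest called changes in each direction were named that had the same direction in all 3 lines or days, were well above background on all arrays of the higher group and had an established symbol. Where fewer than 5 qualified, the 5 genes with the smallest p were added. In single-array comparisons the 5 largest and 5 smallest differences were named. Some genes that this rule selects are not reported here.

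Alternatives were normexp background correction (offset 50), quantile normalization, scaling to detected probes, the authors' value table, no filter, a filter on all 9 arrays, floors of 1 and 20, the mean of probes, trend and robust moderation, array weights, no block, only the 6 arrays compared, the slide as a block, leaving out each line or day, and thresholds of 0.1 or an added 2-fold change. The files held no mean foreground column, so normexp used the median foreground and background columns. Array weights gave convergence warnings. Leaving out each array was added after seeing the data, because the day 7 arrays of both knock-in lines and the wild type day 3 array stood apart. Overlaps of calls that share controls were compared with 50 simulations of unchanged groups.

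To test the method, genes and 1 list were shifted in simulated arrays without the real group differences. Of genes shifted by 1, 2 and 3 (log2), 4.48 to 22.4, 55.2 to 76.1 and 74.2 to 84.8 percent were called across contrasts. None had the wrong sign, and 3 to 9 unchanged genes were called. A list shifted by 1 was called in all 6 contrasts, beside 1 other list in PKM1 knock-in against wild type and 0 in the rest. This does not bound false list calls in real arrays. Of the named genes with several probes that passed the filter, at most 2 in a contrast had a probe of opposite sign.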

Results

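Total RNA was profiled from 3 mouse embryonic stem (ES) cell lines, a wild type line, a PKM1 knock-in line and a PKM2 knock-in line. PKM1 and PKM2 are alternative splice forms of the glycolytic enzyme pyruvate kinase M, both encoded by Pkm. Each line was sampled undifferentiated in the presence of LIF (day 0) and as embryoid bodies, floating aggregates that differentiate after LIF is withdrawn, at day 3 and day 7. The stated purpose was to follow differentiation into the germ layers in these lines. One-colour Agilent mouse arrays were used, 9 in all, with 1 array per line and day. There were therefore no repeats of any line and day: the 3 lines served as the repeats of a day and the 3 days as the repeats of a genotype. Every p-value measures only the spread between these arrays, and a genotype is represented by 1 cell line.

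Between 54.2 and 61.6 percent of the spots on an array were well above background and 0 were saturated. Correlations of log2 signal between arrays ranged from 0.892 to 0.984 over the 15011 genes tested. The first principal component held 39.6 percent of the variance. On it, the day 3 arrays lay between 48.3 and 62.7, the day 0 arrays between -20.0 and -1.29, and the day 7 arrays at -109 for the PKM1 knock-in line, -56.5 for wild type and 22.4 for the PKM2 knock-in line. The number of arrays limits the precision: the median standard error of a log2 change was 0.260. Slide 1 held 5 arrays and slide 2, scanned on another day, held 3, and the PKM2 knock-in day 7 array was alone on slide 3. Values with the slide as a block leave that array out.

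Pkm, the edited gene, was measured by 1 probe that was well above background on all 9 arrays. Its log2 signal at days 0, 3 and 7 was 13.64, 16.10 and 14.66 in the wild type line, 13.58, 14.72 and 13.93 in the PKM1 knock-in line, and 13.78, 14.30 and 13.60 in the PKM2 knock-in line. The probe cannot check the knock-in, because where it lies relative to the alternative exons was not determined here. None of the Pkm differences passed the test. Against wild type the log2 difference was -0.73 ± 0.36 (SE, n = 3 days) in the PKM1 knock-in line (limma adjusted p = 0.488, lower on 3 of 3 days) and -0.91 ± 0.36 in the PKM2 knock-in line (adjusted p = 0.351, lower on 2 of 3 days). Between the knock-in lines it was -0.18 (adjusted p = 0.890). Blocked by slide, these values were -0.89, -0.67 and 0.22. Within slide 1 the PKM2 knock-in line exceeded wild type by 0.14 at day 0 and differed from the PKM1 knock-in line by -0.42 at day 3. From day 0 the Pkm difference was 1.38 ± 0.36 at day 3 (adjusted p = 0.0821, higher in 3 of 3 lines, n = 3 lines) and 0.40 at day 7 (adjusted p = 0.622). Pklr, the pyruvate kinase gene of liver and red cells, was not well above background on any array.

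**Figure D1:**
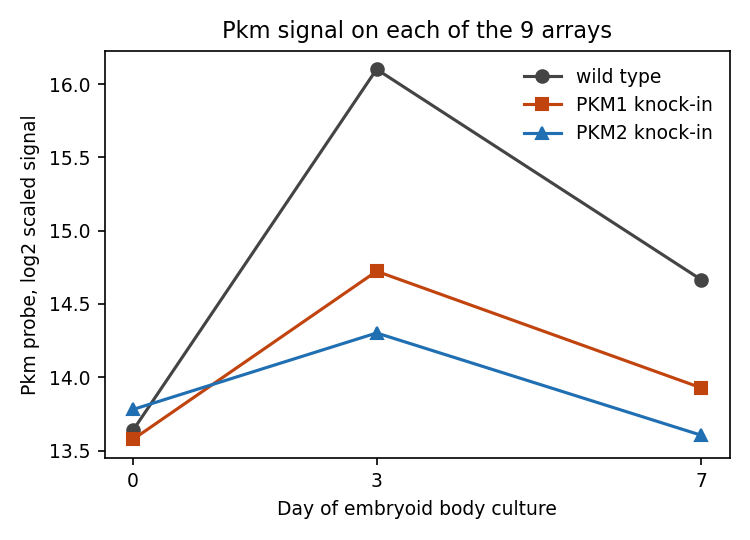
Log2 scaled signal of the Pkm probe (vertical axis) at days 0, 3 and 7 (horizontal axis) in each line, 1 array per point. The 3 lines lie between 13.58 and 13.78 at day 0, and at day 3 the wild type array reads 16.10 against 14.72 and 14.30 in the knock-in lines.

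The comparison of day 3 with day 0 asked which genes moved in early embryoid bodies in all 3 lines. Fos, Fosb and Egr2, which encode transcription factors induced within minutes by growth stimuli, fell with the inflammatory mediators Il6, Cxcl1 and Ccl7. Bcl11a and Lef1, which encode transcription factors, rose with Lefty1, an antagonist of Nodal signalling. Il6 was at least 19.5-fold lower (log2 change -6.18 ± 0.32, SE, n = 3 lines, adjusted p = 0.00334), and Fos was 171-fold lower (-7.42 ± 0.70, adjusted p = 0.0124). Bcl11a was at least 20.3-fold higher (5.13 ± 0.44, adjusted p = 0.00998). Where no array of the dimmer group was well above background, a ratio is written as at least N-fold. The brighter group's mean is set against the higher of the array's lowest detected signal and the probe's own signal. Folds at the detection limits do the same for each undetected array of a dimmer group measured on only 1 or 2 of 3 arrays. In limma, 615 of 15011 genes passed, 282 higher and 333 lower, and each of the 615 moved the same way in all 3 lines. At an unadjusted p under 0.05 there were 3930, where chance gives 750.6.

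The other large falls, each with its adjusted p, were of Cxcl1 (at least 39.1-fold, 0.0209), Egr2 (55.1-fold, 0.0351), Ccl7 (49.1-fold, 0.0336) and the matrix proteoglycan gene Dcn (73.5-fold, 0.0391). Falls were also large for Slpi (at least 23.3-fold, 0.0162), Ifi27 (63.6-fold, 0.0147), Mmp3 (35.4-fold, 0.0239) and Fosb (54.5-fold, 0.0286). Large rises followed for Lef1 (18.1-fold, 0.019), the cartilage protein gene Ucma (at least 5.33-fold, 0.0147), the noncoding RNA Platr5 (9.58-fold, 0.0124), Jakmip2 (10.2-fold, 0.0183), and Lefty1 (14.3-fold, 0.0476). They also followed for Aass (12.6-fold, 0.0313), Duxbl2 (12.2-fold, 0.0229), Spata45 (at least 5.61-fold, 0.00998) and Thbs4 (at least 3.57-fold, 0.019). The folds of Egr2, Ccl7 and Jakmip2 (1 of 3 dimmer arrays measured) and of Mmp3, Lef1 and Platr5 (2 of 3) are at the detection limits. Within slide 1, where days 0 and 3 of the PKM2 knock-in line lay side by side, the rising genes measured on both arrays differed by 3.30 (Lefty1) to 5.07 (Lef1) and such falling ones by -2.34 (Dcn) to -5.14 (Fos). The slide block left the log2 changes identical by design. Aass (adjusted p = 0.0512), Egr2 (0.0523) and Dcn (0.0673) then missed the threshold, and 580 genes were called, 365 of them among the 615.

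**Figure D2:**
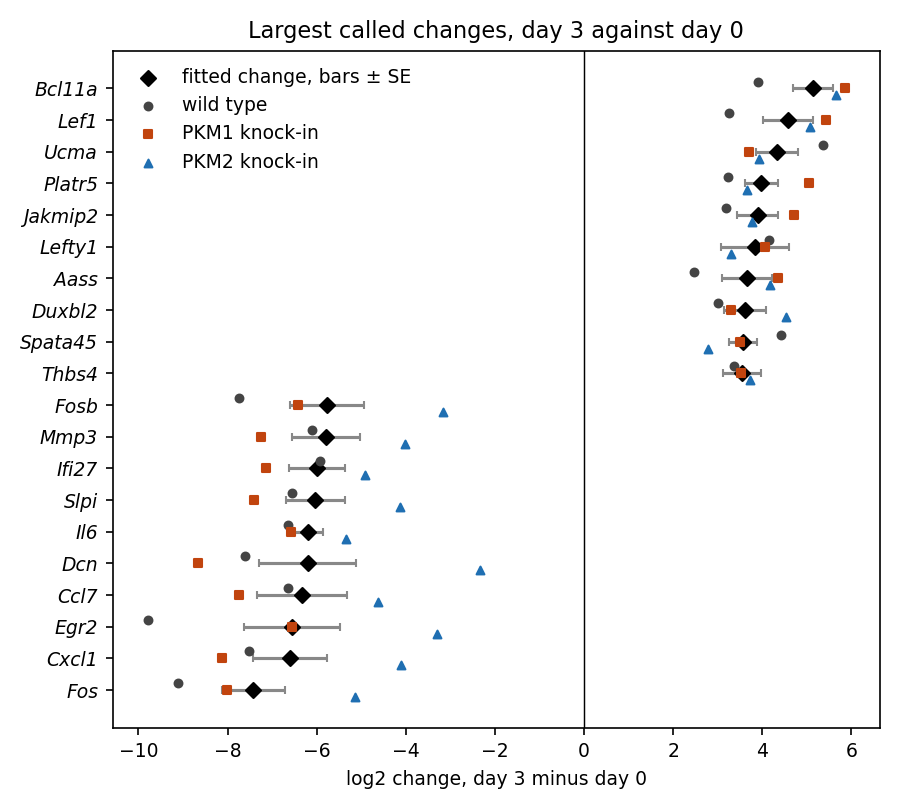
Log2 change from day 0 to day 3 (horizontal axis) of the 10 rising and 10 falling genes with the largest called changes, as diamonds with bars of 1 SE and a marker for each line. Every gene moves the same way in the 3 lines, from Fos at -7.42 to Bcl11a at 5.13.

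The fibroblast, stress response, Hox and interferon lists shifted lower at a preset correlation, each with adjusted p = 0.472 with an estimated correlation. Of 19 fibroblast and feeder cell genes, 18 were lower at day 3 and 6 passed over all genes tested (10 adjusted over the list alone). The median log2 change was -1.98 (-2.08 within slide 1). Among them the collagen genes Col1a2 and Col6a1 fell 21.5-fold and (at the detection limits, 1 of 3 arrays measured) 14.1-fold, Dcn fell as above, and Ptx3 fell at least 3.32-fold. All 21 integrated stress response genes were lower, 11 of them called (14 adjusted over the list alone, median -1.55, within slide 1 -1.06). The largest falls were of the transcription factor gene Atf3 (38.0-fold), the lipoprotein receptor gene Vldlr (12.4-fold), Nupr1 (8.67-fold) and the cystine transporter gene Slc7a11 (at least 1.96-fold). Of 16 Hox genes, which pattern the body axis, 15 were lower and members such as Hoxb9 (at least 9.63-fold) and Hoxc4 (at least 3.75-fold) fell (3 called, 9 adjusted over the list alone, median -1.68, also -1.68 within slide 1). Of 19 interferon response and MHC class I genes, 14 were lower and 5 fell (6 lower and 1 higher adjusted over the list alone, median -0.83, within slide 1 -0.41). They included Usp18 (at least 10-fold), Ifit3 (at least 4.39-fold), Isg15 (6.14-fold) and B2m (4.94-fold). The call of Usp18 was lost in 8 and that of Ptx3 in 9 of 13 alternatives (adjusted p up to 0.101 and 0.109). Camera with a preset correlation gave adjusted p of 2.64e-08 for fibroblast, 8.24e-13 for stress response, 3.83e-07 for Hox and 0.000544 for interferon lists.

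The LIF target and naive pluripotency lists also shifted lower. All 13 LIF and STAT3 targets were lower, with Klf4 down 4.37-fold and the feedback inhibitor gene Socs3 down 3.03-fold (2 called, 5 adjusted over the list alone, median -0.64, within slide 1 -0.98, adjusted p = 2.08e-05; adjusted p = 0.305 with an estimated correlation). Of 18 naive pluripotency genes, 15 were lower and Klf4 and Tbx3 (2.91-fold) fell (2 called and 2 adjusted over the list alone, median -0.60, within slide 1 -0.54, adjusted p = 0.00121; adjusted p = 0.727 with an estimated correlation). The mesoderm list fell (12 of 15 lower, median -1.10, within slide 1 -0.76, adjusted p = 0.000995; adjusted p = 0.478 with an estimated correlation). Foxc2 (at least 3.26-fold) was its only called member over all genes, with 6 lower and 1 higher adjusted over the list alone. The trophoblast list (11 of 11 lower, median -1.04, within slide 1 -1.90) and the epithelial to mesenchymal transition list (14 of 14 lower, median -0.76, within slide 1 -0.65) shifted with adjusted p of 0.00634 and 0.0065, and with adjusted p = 0.528 and 0.696 with an estimated correlation. Neither had a member called, over all genes or adjusted over the list alone. Their largest values were -1.96 ± 0.70 for Esx1, -1.67 ± 0.96 for Gata3, -4.02 ± 1.11 for Ccn1 and -2.32 ± 0.81 for Ccn2. These shifts stood beside the fall of the fibroblast and feeder list given above.

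The cholesterol, pentose phosphate, fatty acid and formative epiblast lists shifted higher. All 21 cholesterol synthesis genes were higher at day 3 and 8 were called (19 adjusted over the list alone, median 1.63, within slide 1 1, adjusted p = 1.82e-10; adjusted p = 0.472 with an estimated correlation). These included the enzyme genes Dhcr7 (4.35-fold) and Lss (3.97-fold). Of 11 pentose phosphate pathway genes, 9 were higher and G6pd2 (2.69-fold), G6pdx (2.25-fold) and Pgd (2.16-fold) rose (3 called, 6 adjusted over the list alone, median 0.93, within slide 1 0.57, adjusted p = 0.00793; adjusted p = 0.472 with an estimated correlation). Of 26 fatty acid genes, 19 were higher and 4 rose. These were Acaca (3.78-fold), Fads2 (3.51-fold), Acsl4 (2.90-fold) and Scd2 (2.73-fold), with 8 adjusted over the list alone (median 0.39, within slide 1 0.40, adjusted p = 0.0151). Of 11 formative epiblast genes, which mark exit from naive pluripotency, 9 were higher and Lef1 and the DNA methyltransferase gene Dnmt3b (4.45-fold) rose (2 called, 4 adjusted over the list alone, median 1.61, within slide 1 1.79, adjusted p = 0.00989). Both lists had adjusted p = 0.587 with an estimated correlation.

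All 25 ribosome biogenesis and Myc target genes were higher, with Myc (3.12-fold) and Nolc1 (2.85-fold) called and 6 passing adjusted over the list alone (median 0.73, within slide 1 0.39, adjusted p = 6.49e-05; adjusted p = 0.727 with an estimated correlation). The cell cycle list (35 of 37 higher, median 0.44, within slide 1 0.08) and the oxidative phosphorylation list (52 of 66 higher, median 0.30, within slide 1 0.27) shifted with adjusted p of 0.000933 and 0.0065. Each had adjusted p = 0.849 with an estimated correlation and 0 members called, over all genes or adjusted over the list alone. Their largest values were 1.78 ± 0.37 for the cyclin gene Ccne1, 1.13 ± 0.25 for Rrm1, 0.91 ± 0.23 for Cox7a2 and 0.86 ± 0.23 for Uqcr11.

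Glycolysis did not shift as a list (18 of 24 higher, median 0.59, within slide 1 0.14, adjusted p = 0.0688). Pfkm (log2 change 1.24, adjusted p = 0.0368) and Eno3 (1.03, adjusted p = 0.0476) rose and 8 members were higher and 2 lower adjusted over the list alone. The medians of 18 other uncalled lists lay between -0.66 (neural crest) and 0.39 (Pkm splicing regulators). In 5 further uncalled lists, with medians between -0.04 and 0.14, the median, mean and test differed in sign. Called members of these lists included the imprinted genes Nnat (2.51), Plagl1 (-1.67) and Snrpn (1.05), the one-carbon genes Aldh1l2 (-3.80), Aldh1l1 (-1.33), Ahcy (1.26) and Mthfd2 (-1.10), as log2 changes. Others were the mitochondrial Pck2 (-2.21) and the alanine transaminase gene Gpt (0.97), Asns (-1.55), Srm (1.40) and Bcat2 (1.16). Called too were the TGF-beta regulators Skil (1.42) and Id4 (-1.24), the endothelial Cldn5 (1.92) and the germline Piwil2 (-1.53).

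In all, camera called 16 of 40 lists, 7 higher and 9 lower, with 17 called when the slide was a block. With an estimated correlation 0 were called (3 at an unadjusted p under 0.05), and fry called 7. The gene count rested on single arrays. Limma called 0 without the wild type or the PKM1 knock-in line (1762 and 2429 at an unadjusted p under 0.05). It called 281 without the PKM2 knock-in line, 17, 9 and 163 without the wild type array of day 0, 3 or 7, 2 and 5 without the PKM1 knock-in array of day 0 or 3, and 108, 133 and 1257 without the PKM2 knock-in array of day 0, 3 or 7. List calls were lost for oxidative phosphorylation (adjusted p = 0.585 with quantile normalization, 0.167 without the wild type line, and 0.0567, 0.104 and 0.168 without the wild type day 0, wild type day 3 or PKM2 knock-in day 0 array). Without the PKM2 knock-in day 0 array they were lost for trophoblast (0.0985), epithelial to mesenchymal transition (0.132) and fatty acid genes (0.0546). Epithelial to mesenchymal transition was lost without the wild type day 3 array (0.0685), formative epiblast without the PKM2 knock-in day 3 array (0.075). Formative epiblast (0.0934) and mesoderm (0.0634) were lost when genes had to be well above background on all 9 arrays.

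By day 7 the visceral endoderm genes of the yolk sac were the list farthest above day 0. The extraembryonic endoderm list rose (23 of 24 higher, median log2 change 3.62, camera adjusted p = 1.63e-10), while adjusted p = 0.776 with an estimated correlation. The medians per line were 7.43 in PKM1 knock-in, 2.27 in wild type and 0.77 in PKM2 knock-in. Its largest values were 8.64 ± 2.17 (SE, n = 3 lines) for Afp and 8.17 ± 1.24 for the thyroxine carrier gene Ttr, at least 111-fold and 116-fold, with adjusted p of 0.189 and 0.1 in limma. No member was called over all genes tested and 15 passed adjusted over the list alone. Under the slide block the median was 4.84 (adjusted p = 1.76e-12), and within slides it was 2.27 (slide 1, wild type) and 7.43 (slide 2, PKM1 knock-in).

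The genes called at day 7 included Mgp, Il6 and Col6a3, which fell, and Car14, which rose. In limma 14 of 15011 genes differed from day 0, 1 higher and 13 lower (2152 at an unadjusted p under 0.05), all in the same direction in 3 of 3 lines. The carbonic anhydrase gene Car14 rose 13.0-fold (3.76 ± 0.37, adjusted p = 0.0381). Falls were found for Mgp, an inhibitor of calcification (113-fold, -7.09 ± 0.59, adjusted p = 0.0289), Il6 (at least 21.2-fold, -5.92 ± 0.32, adjusted p = 0.00412) and the growth factor gene Ereg (at least 14.8-fold). They were also found for the neuropeptide gene Npy (at least 7.69-fold), the collagen gene Col6a3 (7.23-fold, -3.74 ± 0.18, adjusted p = 0.00411), Cavin2 (9.44-fold), the BMP antagonist gene Grem1 (11.7-fold), Ifi207 (at least 3.61-fold), Mst1 (6.95-fold) and Ecel1 (6.82-fold). Folds at the detection limits are those of Mgp and Col6a3 (1 of 3 dimmer arrays measured) and of Car14, Cavin2 and Mst1 (2 of 3). Where both arrays measured the gene, differences within slide 1 (wild type) and slide 2 (PKM1 knock-in) ranged from -2.33 for Mst1 on slide 2 to -7.34 for Mgp on slide 1, with Car14 at 3.09 on slide 1. With the slide as a block 10 genes were called, 6 higher and 4 lower, 4 of them among the 14. Mgp, Il6, Col6a3 and Ifi207 kept an adjusted p under 0.05 (0.0325 for Mgp, 0.0485 for the others), and Car14 had 0.0682. The fibroblast and feeder list as a whole did not shift at day 7 (median -0.12, adjusted p = 0.207, 0.24 with the slide as a block), with line medians of 0.16, 0.23 and -2.32 in wild type, PKM1 and PKM2 knock-in.

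The definitive endoderm and formative epiblast lists shifted higher as well. The definitive endoderm, formative epiblast, naive pluripotency, stress response, germline and interferon lists had adjusted p = 0.776 with an estimated correlation. Cell cycle and ribosome lists had 0.820. The definitive endoderm list rose (9 of 11 higher, median 0.94, adjusted p = 0.00224), with 0 members called and 5 passing adjusted over the list alone. The values of the pioneer factor gene Foxa2 and of Sox17 were 5.45 ± 1.18 and 4.81 ± 1.44. The formative epiblast list rose (10 of 11 higher, median 0.85, adjusted p = 0.000827; 2 adjusted over the list alone), with 4.6 ± 1.09 for Fgf5 and 2.93 ± 0.56 for Lef1. The LIF and STAT3 list shifted lower (12 of 13 lower, median -1.27, adjusted p = 3.38e-07; adjusted p = 0.158 with an estimated correlation; 7 adjusted over the list alone), with -2.32 ± 0.28 for Socs3 and -2.05 ± 0.46 for Junb. The naive pluripotency list shifted lower (18 of 18 lower, median -0.90, adjusted p = 2.1e-05; 1 adjusted over the list alone), with -1.65 ± 0.28 for Klf4 and -1.46 ± 0.73 for Dppa3. Falls were also called for the integrated stress response (17 of 21 lower, median -0.55; 4 adjusted over the list alone; Slc7a11 -1.94, Cth -1.23) and the germline list (12 of 13 lower, median -0.41; 3 adjusted over the list alone; Tex11 -1.45, Piwil2 -1.32). The cell cycle list (35 of 37 lower, median -0.36; Mcm5 -0.74, Cdc20 -0.71) and the ribosome list (22 of 25 lower, median -0.32; Mycn -0.81, Rrs1 -0.65) fell with no member passing adjusted over the list alone. The interferon list fell (14 of 19 lower, median -0.52; 1 adjusted over the list alone). Its largest value was 2.77 ± 1.46, for Cxcl10, beside -1.90 for Ifit3. No member of these lists was called over all genes tested.

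Under the slide block and within slides 1 and 2, the medians were 1.45, 1.60 and 2.10 for definitive endoderm, 1.09, 0.97 and 1.20 for formative epiblast, -1.12, -0.88 and -1.03 for LIF targets, and -1.33, -0.62 and -2.03 for naive pluripotency. They were -0.56, -0.51 and -0.76 for the stress response, -0.50, -0.81 and -0.23 for germline, -0.59, -0.39 and -0.64 for cell cycle, -0.49, -0.09 and -0.67 for ribosome biogenesis and -0.49, -0.60 and -0.42 for the interferon list. Of these list calls the block ended only that of the interferon list (adjusted p = 0.219), while 18 lists were called with it against 10 without. Fry called 1 list, and camera with an estimated correlation 0 (1 at an unadjusted p under 0.05). In limma 0 genes were called without the wild type line, the PKM1 knock-in line or the day 0 array of either (1291, 1086, 1747 and 1094 at an unadjusted p under 0.05). It called 93 without the PKM2 knock-in line, 3 without the wild type day 3 or day 7 array, 4 and 9 without the PKM1 knock-in day 3 or day 7 array, and 7 and 225 without the PKM2 knock-in day 3 or day 7 array. The list count was 18 without the PKM2 knock-in day 7 array and 20 without that line. Calls were lost for ribosome biogenesis (adjusted p = 0.504, 0.135, 0.0654 and 0.524 without the PKM1 knock-in day 7, PKM1 knock-in day 0 or PKM2 knock-in day 0 array or the PKM1 knock-in line, 0.0771 with array weights). They were lost for interferon (0.142, 0.201, 0.104 and 0.07 without the wild type day 0 or PKM2 knock-in day 7 array or either of those lines), germline (0.0604 and 0.0712 without the PKM2 knock-in day 0 array or line). Interferon and definitive endoderm (0.173 for both) were lost when genes had to be well above background on all 9 arrays.

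**Figure D3:**
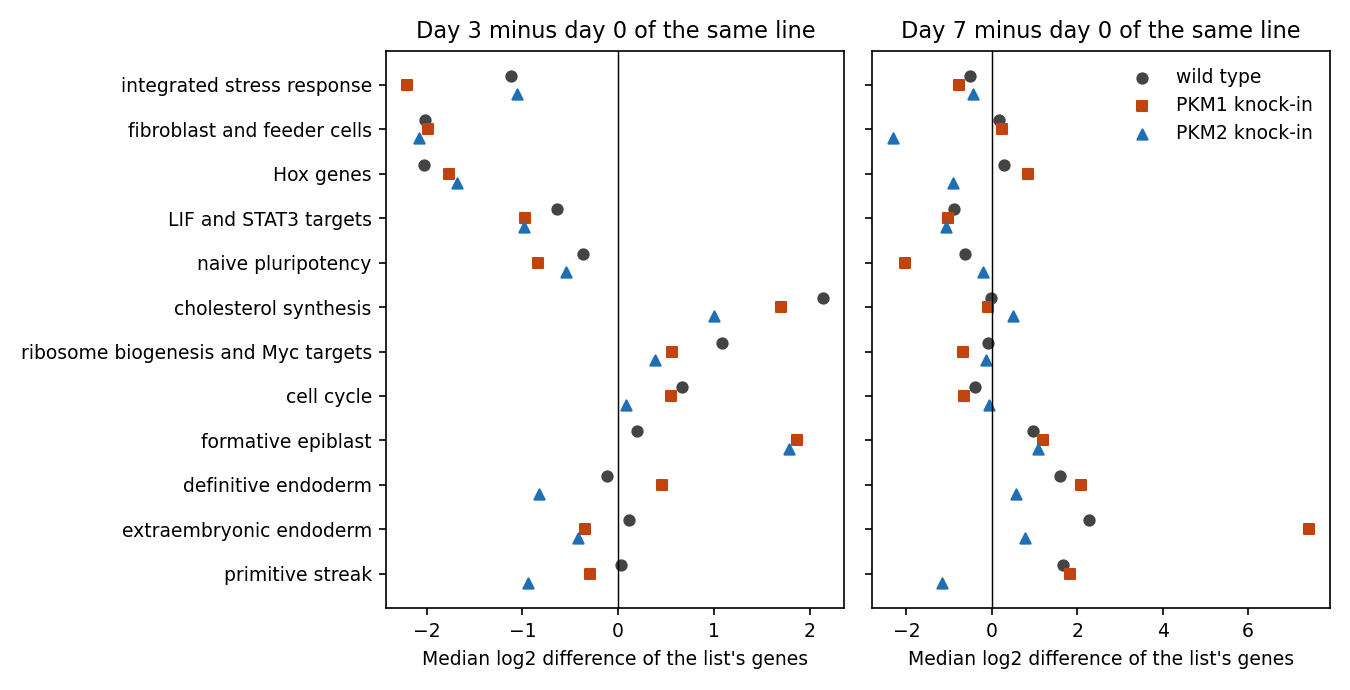
Median log2 change of 12 gene lists (vertical axis, by list) from day 0 to day 3 and from day 0 to day 7 (horizontal axis), with a marker for each line. At day 7 the extraembryonic endoderm medians are 7.43, 2.27 and 0.77 in the PKM1 knock-in, wild type and PKM2 knock-in lines, and the fibroblast and feeder medians 0.23, 0.16 and -2.32.

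Day 7 was then set against day 3, the step in which germ layer genes would appear. The Hox gene Hoxb9 stood at least 13.6-fold above day 3 (4.50 ± 0.36, SE, n = 3 lines, higher in 3 of 3), but like every gene it missed the threshold. In limma 0 genes passed, with a smallest adjusted p of 0.0579 and 4550 genes at an unadjusted p under 0.05. The genes with the smallest p besides Hoxb9 were Nxpe4 (2.82 ± 0.25), Sobp (2.87 ± 0.27), Jph4 (-2.33 ± 0.22) and Ccno (-2.89 ± 0.27), all at adjusted p = 0.0579. With the slide as a block, which leaves out the day 7 array of the PKM2 knock-in line, 984 genes were called, 697 higher and 287 lower, with adjusted p of 0.0144 (Hoxb9) to 0.0292 (Jph4) for these 5. The count was 2393 without the PKM2 knock-in day 7 array, 1457 without that line and 2 without the PKM1 knock-in day 7 array. No slide held a day 3 and a day 7 array of 1 line.

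Of 40 lists, 17 shifted between day 3 and day 7, 11 higher and 6 lower. With an estimated correlation the adjusted p was 0.5 for each of the 11 but imprinted genes (0.644). All 24 extraembryonic endoderm genes were higher (median 4.26, adjusted p = 3.38e-11; 18 adjusted over the list alone; Afp 8.71 ± 2.17, Ttr 8.15 ± 1.24). So were 10 of 11 definitive endoderm genes (median 1.26, adjusted p = 0.000805; 4 alone; Sox17 4.99 ± 1.44, Foxa2 4.91 ± 1.18) and 12 of 15 mesoderm genes (median 1.37, adjusted p = 0.000805; 4 higher and 1 lower alone; Pdgfra 4.28 ± 1.63, Hand1 3.00 ± 0.99). Also higher were 11 of 16 cardiac muscle genes (median 0.60, adjusted p = 0.0387; 3 higher and 1 lower alone; Myl3 4.64 ± 0.91, Gata4 4.41 ± 1.04), 6 of 8 neural crest genes (median 1.38, adjusted p = 0.0291; 3 alone; Sox9 2.29 ± 0.71, Msx2 2.10 ± 0.58) and 9 of 11 trophoblast genes (median 0.97, adjusted p = 0.00401; 0 alone; Gata3 3.14 ± 0.96). Alone stands here for adjusted over the list alone, and no member of any list passed over all genes tested. Hox genes rose as a list (15 of 16 higher, median 1.58, adjusted p = 3.94e-07; 10 alone; Hoxb4 3.59 ± 0.65). The fibroblast and feeder list rose beside them (18 of 19 higher, median 1.94, adjusted p = 2.27e-06; 5 alone; Acta2 5.94 ± 2.25, Postn 3.65 ± 1.67). Its line medians were 2.24, 2.24 and 0.00 in wild type, PKM1 and PKM2 knock-in. Rises were also called for epithelial to mesenchymal transition genes (14 of 14 higher, median 1.16, adjusted p = 3.62e-05; 0 alone; Ccn1 3.37 ± 1.11, Zeb2 3.06 ± 0.93), the stress response (20 of 21 higher, median 0.92, adjusted p = 2.33e-07; 9 alone; Atf3 4.16 ± 0.99, Vldlr 3.64 ± 0.50) and imprinted genes (16 of 27 higher, median 0.33, adjusted p = 0.045; 4 higher and 2 lower alone; the growth factor gene Igf2 4.85 ± 1.11, Sgce 2.71 ± 0.67).

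Cell cycle, ribosome biogenesis, cholesterol and energy metabolism lists fell over the same interval. With an estimated correlation the adjusted p was 0.597 for cell cycle, 0.563 for ribosome biogenesis, 0.715 for the tricarboxylic acid cycle, 0.734 for oxidative phosphorylation and 0.5 for cholesterol and pentose phosphate genes. All 37 cell cycle genes were lower (median -0.84, adjusted p = 3.2e-09; 29 adjusted over the list alone; Ccne1 -2.35 ± 0.37, Rrm2 -1.25 ± 0.30). So were all 25 ribosome biogenesis genes (median -0.97, adjusted p = 4.9e-08; 20 alone; Ddx21 -1.53 ± 0.35, Nolc1 -1.46 ± 0.30) and all 21 cholesterol synthesis genes (median -1.35, adjusted p = 1.08e-07; 16 alone; Idi1 -2.47 ± 0.44, Lss -1.94 ± 0.38). Lower as well were 63 of 66 oxidative phosphorylation genes (median -0.39, adjusted p = 6.78e-05; 0 alone; Atp5g1 -0.86, Cycs -0.83), 22 of 23 tricarboxylic acid cycle genes (median -0.41, adjusted p = 0.00771; 0 alone; Idh3a -0.95, beside 0.88 for Idh2) and 9 of 11 pentose phosphate genes (median -0.79, adjusted p = 0.0203; 5 alone; Prps1 -1.40, G6pd2 -1.09). Camera called 0 lists with an estimated correlation (0 at an unadjusted p under 0.05), and fry 0 (18 at an unadjusted p under 0.05).

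The slide block called 20 lists between day 3 and day 7. The medians were then 5.33 for extraembryonic endoderm, 2.06 for definitive endoderm, 2.33 for mesoderm, 0.68 for cardiac muscle, 1.95 for neural crest, and 1.33 for trophoblast. They were 2.22 for Hox genes, 1.98 for fibroblast and feeder genes, 2.16 for epithelial to mesenchymal transition, 0.62 for the stress response, and 0.73 for imprinted genes. Among falling lists they were -1.12 for cell cycle, -1.17 for ribosome biogenesis, -1.60 for cholesterol synthesis, -0.57 for oxidative phosphorylation, -0.51 for the tricarboxylic acid cycle and -0.61 for the pentose phosphate pathway. Only the last of these calls was lost (adjusted p = 0.056, and 0.0539 without the PKM2 knock-in day 7 array). Quantile normalization ended the calls of cardiac muscle (adjusted p = 0.214), neural crest (0.108), imprinted genes (0.0607), the tricarboxylic acid cycle (0.350) and oxidative phosphorylation (0.391). Without the wild type day 7 array, imprinted genes (0.368), neural crest (0.062) and cardiac muscle (0.0518) missed the threshold. So did imprinted genes (0.22) and cardiac muscle (0.0605) without the wild type day 3 array, and imprinted genes without the day 0 array of wild type (0.052) or PKM2 knock-in (0.0565). Cardiac muscle was lost without the PKM2 knock-in day 3 array (0.103), and imprinted genes (0.0589) and the tricarboxylic acid cycle (0.0716) without the PKM1 knock-in day 7 array. Leaving out the wild type line gave 0.504 for imprinted genes, 0.0578 for neural crest and 0.0519 for cardiac muscle, and leaving out the PKM1 knock-in line 0.0601 for the tricarboxylic acid cycle. Scaling to detected probes ended the calls of cardiac muscle (0.0518) and imprinted genes (0.0554). Testing without a filter ended those of imprinted genes (0.0587) and neural crest (0.0532). The fit without a block (0.0777) and the fit to the 6 arrays compared (0.059) ended that of imprinted genes. The filter on all 9 arrays ended those of cardiac muscle (0.124), mesoderm (0.232) and definitive endoderm (0.106).

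Over all 3 days together, limma's F test called 179 genes (4487 at an unadjusted p under 0.05; 724 with the slide as a block). It called 0 without the wild type or PKM1 knock-in line or the PKM1 knock-in day 0 or day 3 array (1744, 1964, 3211 and 2335 at an unadjusted p under 0.05). It called 5, 2 and 8 without the wild type day 0, 3 or 7 array, 16 without the PKM2 knock-in day 0 or day 3 array, 716 without the PKM2 knock-in line and 2009 without its day 7 array. All 14 genes called at day 7 against day 0 were also called at day 3 against day 0 in the same direction: 1 of 1 higher and 13 of 13 lower. Independent lists of these sizes would share 0.0188 and 0.288 genes, and simulated unchanged days set against the same day 0 arrays shared a median of 0 and at most 0. Simulations sharing 0 calls do not show what shared controls add to real changes, so part of the excess may come from the shared controls.

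The knock-in lines were compared with wild type to ask which genes differed at all 3 days. Mest, an imprinted gene expressed from the paternal allele, was 101-fold higher in the PKM1 knock-in line (6.66 ± 0.31, SE, n = 3 days, limma adjusted p = 0.0034) and 113-fold higher in the PKM2 knock-in line (6.82 ± 0.31, adjusted p = 0.00289). Nudt12, which encodes an NADH pyrophosphatase of peroxisomes, was not well above background in wild type and was at least 5.54-fold and 5.65-fold higher in the PKM1 and PKM2 knock-in lines (3.99 ± 0.27, adjusted p = 0.0191, and 4.02 ± 0.27, adjusted p = 0.0183). Both genes were higher in each knock-in line on 3 of 3 days, and they were the only 2 called in either comparison with wild type (1849 and 2011 genes at an unadjusted p under 0.05) and in limma's F test over the genotypes (1932). The 2 shared calls compare with 0.000266 for independent lists and a simulated median of 0 and highest of 0 for unchanged lines against the same wild type arrays, with the same limit. Part of the excess may come from the shared controls.

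**Figure D4:**
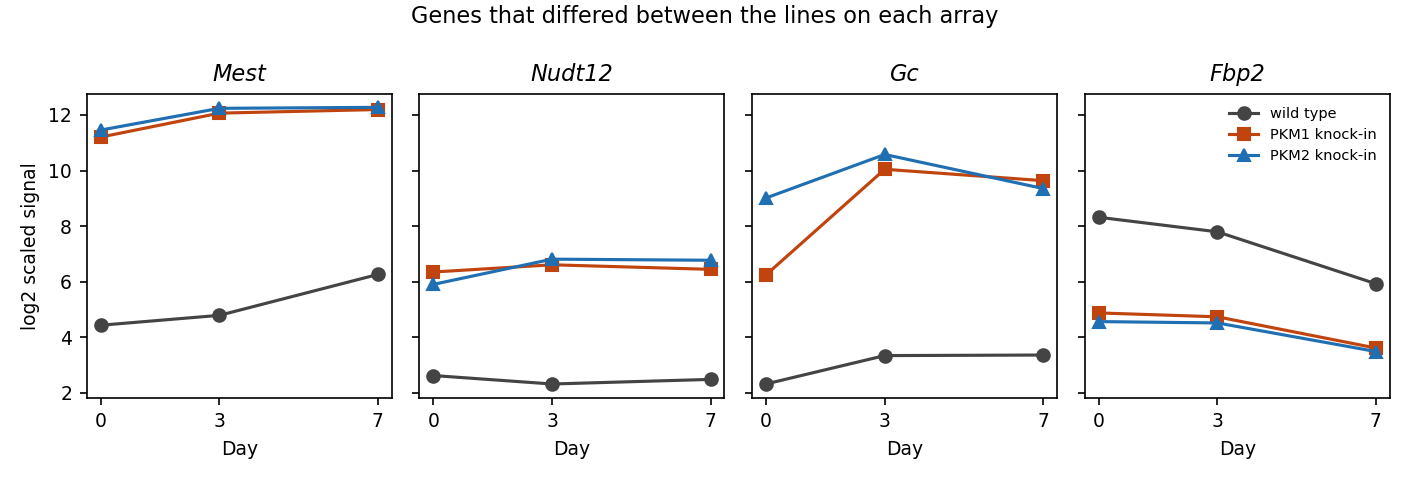
Log2 scaled signal (vertical axis) of Mest, Nudt12, Gc and Fbp2 at days 0, 3 and 7 (horizontal axis) in each line, 1 array per point. Mest reads 4.43 to 6.26 in wild type and 11.20 to 12.27 in the knock-in lines. Another Gc probe, not shown, was well above background only on the PKM1 knock-in day 7 array.

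Several further genes lay close to the threshold without passing. The vitamin D binding protein gene Gc differed from wild type by 5.63 ± 0.61 in the PKM1 knock-in line (at least 25-fold, adjusted p = 0.0982) and by 6.64 ± 0.61 in the PKM2 knock-in line (at least 50.2-fold, adjusted p = 0.0674). Fbp2, which encodes the muscle form of the gluconeogenic enzyme fructose bisphosphatase, differed by -2.94 ± 0.28 (adjusted p = 0.0908) and -3.16 ± 0.28 (adjusted p = 0.0674). The others with the smallest p were Lrrn2 (-2.80 ± 0.26), Ttll9 (-1.74 ± 0.18) and Zfp981 (-1.70 ± 0.18) in the PKM1 knock-in line, with adjusted p between 0.0908 and 0.0982. In the PKM2 knock-in line they were the collagen gene Col6a3 (-1.88 ± 0.18, adjusted p = 0.0674), Zfp750 (-2.13 ± 0.22, adjusted p = 0.0927) and Nfasc (-1.94 ± 0.21, adjusted p = 0.0958). Blocked by slide, the values were 6.81 (adjusted p = 0.0296) for Mest, 4.06 (adjusted p = 0.194) for Nudt12, 5.90 for Gc and -2.97 for Fbp2 in the PKM1 knock-in line, and 6.90 (adjusted p = 0.0559), 3.80 (adjusted p = 0.350), 6.85 and -3.33 in the PKM2 knock-in line. In turn 1 and 0 genes were then called (1731 and 1385 at an unadjusted p under 0.05). Within slide 1, PKM2 knock-in exceeded wild type at day 0 by 7.02 for Mest and at least 1.86 for Nudt12, and Fbp2 differed by -3.75. No slide held a PKM1 knock-in and a wild type array of 1 day.

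The call of Mest was lost in the PKM1 knock-in comparison without day 0 (adjusted p = 0.153), day 3 (0.410), the wild type day 0 array (0.0672) or the PKM1 knock-in day 3 array (0.0642) and in the fit to the 6 arrays compared (0.0548). It was lost in the PKM2 knock-in comparison without day 0 (0.137), day 3 (0.367), the wild type day 0 array (0.0601) or the PKM2 knock-in day 3 array (0.0682) and in the fit to 6 arrays (0.0598). The log2 difference of Mest in these leave-out fits lay between 6.35 and 6.75. Nudt12 was called in 1 of its 12 leave-out fits in each comparison (adjusted p up to 0.595 and 0.505). Nudt12 missed the threshold with a floor of 1 (0.0779 and 0.0589), with a floor of 20 (0.0894 and 0.0934), without a filter (0.0893 and 0.0859) and in the fit to 6 arrays (0.0548 and 0.223). With normexp Nudt12 differed by 1.49 (adjusted p = 0.0797) and 1.45 (adjusted p = 0.0519). Limma called 0 genes in the PKM1 knock-in comparison without day 0, day 3, the wild type day 0 array or the PKM1 knock-in day 3 array (1041, 1166, 1284 and 1471 at an unadjusted p under 0.05). It called 0 in the PKM2 knock-in comparison without day 0, day 3, the wild type day 0 array or the PKM2 knock-in day 3 array (1490, 1232, 1496 and 1889). It called 0 over the genotypes in the F test without day 0, day 3, the wild type day 0 array or the PKM2 knock-in day 3 array (1234, 1129, 1332 and 1810).

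Of 40 lists, 5 differed between the PKM1 knock-in line and wild type. The p53, 2C-like and Nodal lists had adjusted p = 0.807 with an estimated correlation, and the glycolysis and endoderm lists 0.822. Targets of p53 were lower (19 of 20 lower, median -0.43, camera adjusted p = 0.00064; 2 lower and 1 higher adjusted over the list alone), with -1.48 ± 0.48 for the apoptosis gene Perp and -1.17 ± 0.18 for Ptp4a3. Genes of the totipotent 2C-like state were lower (5 of 6, median -2.07, adjusted p = 0.0265, 3 adjusted over the list alone). Zscan4a differed by -4.05 ± 1.01 and Zscan4f by -3.44 ± 1.16. These rest mostly on days 0 and 3, where PKM1 knock-in was not well above background. Day 7 read 6.01 and 7.38 against 6.96 and 7.42 in wild type. Glycolysis genes were higher (19 of 24 higher, median 0.47, adjusted p = 0.0265; 1 adjusted over the list alone), with 1.33 ± 0.26 for the hexokinase gene Hk2 and 0.97 ± 0.29 for Ldhb. Extraembryonic endoderm genes were higher (23 of 24 higher, median 1.29, adjusted p = 0.041; 0 adjusted over the list alone), with 3.42 ± 1.64 for Apom and 2.96 ± 2.17 for Afp. Nodal, BMP and TGF-beta targets were lower (12 of 15 lower, median -0.30, adjusted p = 0.0423; 0 adjusted over the list alone), with -1.31 ± 0.65 for Smad6. No member passed over all genes tested. The fibroblast and feeder list differed by -0.12 (adjusted p = 0.196).

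Under the slide block the medians were -0.44 for p53 targets and -2.32 for 2C-like genes, both still called, and 0.41 for glycolysis (adjusted p = 0.0555), 0.95 for extraembryonic endoderm (0.0992) and -0.23 for the Nodal list (0.0565). Then 3 lists were called. The endoderm shift came from day 7. Without day 7 its median was -0.29 and without the PKM1 knock-in day 7 array -0.34, both called in the opposite direction (adjusted p = 0.0499 and 0.0361). Without the wild type day 7 array it was 0.59 (0.455). With array weights (0.850), without a block (0.0848) and with the filter on all 9 arrays (0.113) it was not called. Glycolysis missed the threshold without the wild type day 0 array (0.153) or the PKM1 knock-in day 7 array (0.0681), and the 2C-like list with the filter on all 9 arrays (0.527). The Nodal list missed it without day 0 (0.0853), day 7 (0.0987), the wild type day 7 array (0.134), the PKM1 knock-in day 0 array (0.152) or the PKM2 knock-in day 0 array (0.051), with the mean of probes (0.0534) and without a block (0.0953). The count of lists was 16 without the PKM1 knock-in day 7 or the wild type day 3 array, 10 without day 3, and 9 without the PKM1 knock-in day 3 array. It was 8 without day 7 or the PKM2 knock-in day 3 or day 7 array, and 3 without the wild type day 7 array. Camera with an estimated correlation and fry called 0 (1 and 4 at an unadjusted p under 0.05).

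Over the 3 days together, the cell cycle and cholesterol lists were higher in the PKM2 knock-in line than in wild type and the fibroblast list lower. At day 3 alone the medians ran the other way for cell cycle (-0.20), ribosome (-0.24), cholesterol (-0.47), tricarboxylic acid (-0.05) and oxidative phosphorylation genes (-0.05). The fibroblast, p53, cardiac muscle, one-carbon, germline and interferon lists had adjusted p = 0.610 with an estimated correlation. The cell cycle, ribosome, cholesterol and tricarboxylic acid lists had adjusted p = 0.762 with an estimated correlation, and oxidative phosphorylation 0.841. Cell cycle genes were higher (36 of 37, median 0.34, adjusted p = 6.04e-05; Mcm2 1.30 ± 0.26, Gins2 1.01 ± 0.23). So were ribosome biogenesis (23 of 25, median 0.28, adjusted p = 0.0127; Myc 1.01 ± 0.30, Nip7 0.90 ± 0.26) and cholesterol synthesis (19 of 21, median 0.38, adjusted p = 0.0131; Msmo1 1.13 ± 0.35). Higher too were the tricarboxylic acid cycle (20 of 23, median 0.24, adjusted p = 0.0187; Suclg1 1.22 ± 0.24, Idh3a 0.62 ± 0.24) and oxidative phosphorylation (52 of 66, median 0.15, adjusted p = 0.0202; Ndufb2 1.25 ± 0.24, Cycs 1.17 ± 0.22). Serine, glycine and one-carbon genes (17 of 22 higher, median 0.42, adjusted p = 0.0127; Mthfd2l 1.82 ± 0.47, Mthfd2 1.41 ± 0.20) and germline genes (13 of 13 higher, median 0.31, adjusted p = 0.0131; Tex11 1.43 ± 0.48, Hormad1 1.33 ± 0.29) were also higher. Fibroblast and feeder genes were lower (19 of 19, median -1.20, adjusted p = 2.59e-05; Acta2 -2.27 ± 2.25, Col3a1 -2.15 ± 0.86). So were p53 targets (18 of 20, median -0.44, adjusted p = 0.00209; Fas -1.94 ± 0.98, Perp -1.54 ± 0.48), cardiac muscle genes (13 of 16, median -0.64, adjusted p = 0.0127; Myl7 -1.40 ± 0.41, Nkx2-5 -1.31 ± 0.46) and interferon genes (16 of 19, median -0.40, adjusted p = 0.0147; Psmb8 -2.26 ± 0.51, Usp18 -1.98 ± 0.76). No member passed over all genes tested. Adjusted over the list alone, 1 member was higher in the one-carbon, germline and tricarboxylic acid cycle lists and 1 lower in the fibroblast list. There were 1 higher and 1 lower among p53 targets, and 0 in the other lists.

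The list calls depended on day 7: without day 7 camera called 0 of the 40 lists (adjusted p from 0.0648 among the 11 above), with medians of 0.56 for germline, -0.46 for interferon, -0.36 for p53, -0.41 for cardiac muscle and -0.55 for fibroblast genes, and of 0.10 for cell cycle and 0.04 for cholesterol genes. Without the PKM2 knock-in day 7 array it called 2, of the 11 only germline. Medians with the slide as a block, which leaves that array out, and within slide 1 at day 0 were 0.10 and 0.42 for cell cycle, 0.10 and 0.54 for ribosome biogenesis, and 0.12 and 0.52 for cholesterol synthesis. They were 0.15 and 0.30 for the tricarboxylic acid cycle, 0.01 and 0.09 for oxidative phosphorylation, 0.32 and 0.35 for one-carbon genes, and 0.59 and 0.80 for germline. Among lower lists they were -0.43 and -0.41 for fibroblast and feeder genes, -0.35 and -0.57 for p53 targets, -0.33 and -0.17 for cardiac muscle and -0.39 and -0.70 for interferon genes. Under the block 6 lists were called, of the 11 only the one-carbon and germline lists (adjusted p = 0.0178 for both). Leaving out the wild type day 0 array left 4 lists. The lost ones had adjusted p = 0.0564 for cholesterol, germline and one-carbon genes, 0.180 for ribosome and interferon genes, 0.190 for oxidative phosphorylation and 0.136 for the tricarboxylic acid cycle. In contrast 18 were called without day 3 or the wild type day 3 array and 17 without the PKM2 knock-in day 3 array. Calls were also lost without day 0 for cholesterol and the tricarboxylic acid cycle (0.072 for both), germline (0.128), interferon (0.164) and ribosome genes (0.131). They were lost without the PKM2 knock-in day 0 array for cholesterol (0.0571), germline (0.118) and interferon genes (0.0741), and without the wild type day 7 array for cholesterol (0.247) and oxidative phosphorylation (0.0979). Quantile normalization ended the calls of ribosome (0.0524), interferon (0.0543), tricarboxylic acid (0.197) and oxidative phosphorylation genes (0.932). Normexp ended those of cardiac muscle (0.0675), tricarboxylic acid (0.0512) and oxidative phosphorylation genes (0.0937). The filter on all 9 arrays ended those of cardiac muscle (0.165), interferon (0.0954) and oxidative phosphorylation genes (0.0574), and the fit without a block that of cholesterol genes (0.116). Camera with an estimated correlation and fry called 0 (1 and 7 at an unadjusted p under 0.05).

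Between the knock-in lines no gene passed. Limma called 0 (1194 at an unadjusted p under 0.05, 457 with the slide as a block, smallest adjusted p = 0.608). The smallest p were those of Mfsd9 (-1.70 ± 0.18, SE, n = 3 days), Acot2 (-1.43 ± 0.18), Zfp229 (1.53 ± 0.20), Unc93a (2.46 ± 0.34) and Olfr1052 (3.17 ± 0.45), all as PKM2 minus PKM1 knock-in. Camera called 8 lists, each with adjusted p = 0.980 with an estimated correlation. Interferon genes were lower in the PKM2 knock-in line (17 of 19, median -0.59, adjusted p = 0.000239; Usp18 -2.41 ± 0.76, Psmb8 -1.88 ± 0.51). Their median was -0.66 under the slide block (adjusted p = 0.00159) and -0.26 within slide 1 at day 3. Extraembryonic endoderm (24 of 24 lower, median -1.79, adjusted p = 8.21e-06; Thbd -4.11 ± 0.76, Afp -3.89 ± 2.17) and fibroblast and feeder genes (17 of 19 lower, median -0.86, adjusted p = 0.000357; Acta2 -2.42 ± 2.25, Col3a1 -1.97 ± 0.86) were lower too. So were definitive endoderm genes (11 of 11 lower, median -0.71, adjusted p = 0.0168; Foxa3 -1.37 ± 0.50, Sox17 -1.33 ± 1.44). Cell cycle (36 of 37 higher, median 0.30, adjusted p = 3.36e-05; Aurkb 0.78, Pcna 0.62) and ribosome biogenesis genes (20 of 25 higher, median 0.19, adjusted p = 0.0297; Myc 1.01, Dkc1 0.83) were higher. Also higher were general pluripotency (11 of 12 higher, median 0.33, adjusted p = 0.0385; Foxd3 0.95, Dppa2 0.73) and formative epiblast genes (8 of 11 higher, median 0.51, adjusted p = 0.0385; Fgf5 1.32, Sox3 1.31). No member passed over all genes tested, and adjusted over the list alone 1 passed, in the extraembryonic endoderm list.

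Of these 8 calls, 6 ended with the slide as a block. The medians were then 0.11 for extraembryonic endoderm, -0.23 for fibroblast and feeder, 0.09 for definitive endoderm, 0.07 for cell cycle, 0.01 for ribosome and 0.09 for general pluripotency genes (adjusted p between 0.366 and 0.948). That of formative epiblast genes held (0.44, adjusted p = 0.00159). Within slide 1 at day 3 the medians were -0.20, -0.10, -0.13, -0.19, -0.23, 0.02 and 0.58 in that order. The same 6 also ended without day 7 (adjusted p between 0.482 and 0.873) and without the PKM2 knock-in day 7 array (0.141 to 0.823). All of them but cell cycle ended without the PKM1 knock-in day 7 array (0.0569 to 0.846), which left 4 lists. Formative epiblast ended without day 0 (0.251), day 3 (0.275), the day 0 array of either line (0.286 and 0.117) or the PKM2 knock-in day 3 array (0.708). Ribosome genes ended without the PKM2 knock-in day 0 array (0.112) and general pluripotency without the wild type day 3 array (0.0523). Without day 7 the count was 5, and without day 0, day 3 or the PKM2 knock-in day 3 array 13. The same 6 lists were not called with array weights (0.147 to 0.994). Formative epiblast (0.0892) and ribosome genes (0.0719) were not called without a block, formative epiblast not with the filter on all 9 arrays (0.126), and general pluripotency not in the fit to 6 arrays (0.0541). Camera with an estimated correlation and fry called 0 (1 and 1 at an unadjusted p under 0.05).

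At single days the lines were compared array against array, with no replicate check and no p-value. At day 0 the genes farthest above wild type in the PKM1 knock-in line, among those well above background on both arrays, were Mest (6.77), Slc15a2 (3.65), Olfr466 (3.62), Rtbdn (3.10) and Serpina10 (3.06), and the farthest below were Rpl39l (-4.33), Zfp951 (-4.32), Nt5e (-3.66), Fbp2 (-3.44) and Tgtp1 (-3.41). In the PKM2 knock-in line they were Mest (7.02), the Y-linked genes Eif2s3y (5.41) and Ddx3y (4.43), Cd109 (3.79) and Stra8 (3.77), against Dnajb8 (-5.09), Vmn1r197 (-4.98), Agbl3 (-4.88), Lcn2 (-4.68) and Rxfp3 (-4.32). The 2C-like medians were -2.31 and -2.71, below all 10000 random lists of like expression (percentile 0). Glycolysis medians were 0.66 and 0.89, above all (percentile 100). At least 4-fold differences numbered 58 higher and 233 lower in PKM1 knock-in and 121 and 304 in PKM2 knock-in. Of 40 lists 15 and 18 lay outside the central 95 percent of random lists. Percentiles and the 2 expected assume that members vary independently.

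At day 3 the PKM1 knock-in array led with Mest (7.27), Speer4d (4.69), the cardiac transcription factor gene Irx4 (4.24), Aadacl4fm5 (4.13) and Pear1 (4.13), against Zfp951 (-4.39), Wnk4 (-3.96), Mlana (-3.56), Rpl39l (-3.51) and Ifna5 (-3.49) (124 higher, 208 lower, 11 lists). The PKM2 knock-in array led with Mest (7.45), Ebf1 (4), Olfr524 (3.67), Cnr1 (3.66) and Klf15 (3.46), against Oas1a (-5.50), Arl14epl (-4.82), Oas1f (-4.73), Fxyd4 (-4.04) and Fam183b (-4.00) (161 higher, 376 lower, 12 lists). Formative epiblast medians were 0.49 (percentile 99.9) and 1.28 (percentile 100), and 2C-like medians -3.08 and -3.34 (percentile 0 for both).

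At day 7 the lines stood farthest apart, with 484 genes at least 4-fold higher and 209 lower in the PKM1 knock-in line, and 224 higher and 722 lower in the PKM2 knock-in line (16 and 26 lists). The PKM1 knock-in array exceeded wild type most for Aqp8 (9.70), Afp (8.63), the fibrinogen gene Fgb (8.60), Apom (8.45) and Lgals2 (8.31), and was lowest for Pou4f2 (-4.05), Car3 (-3.85), Zfp951 (-3.73) and Sall3 (-3.61). Its extraembryonic endoderm median was 4.16 and its hypoxia median 1.30 (percentile 100 for both), and its general pluripotency median -1, naive pluripotency median -0.75 and neural ectoderm median -0.82 (percentile 0 for all 3). The PKM2 knock-in array led with Mest (6.01), Itgb2 (4.88), Gucy2c (3.85), Cubn (3.80) and Rph3al (3.74) and was lowest for Anxa1 (-8.11), Ly6c1 (-7.56), Prss23 (-7.36), Vgf (-6.22) and Fhl2 (-5.38). Its medians were -2.57 for fibroblast and feeder genes, -1.94 for epithelial to mesenchymal transition, -1.83 for primitive streak and -1.11 for extraembryonic endoderm (percentile 0 for all 4), and 1.03 for cholesterol synthesis and 0.80 for cell cycle (percentile 100 for both). Its array was alone on its slide, so slide and array cannot be told apart.

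**Figure D5:**
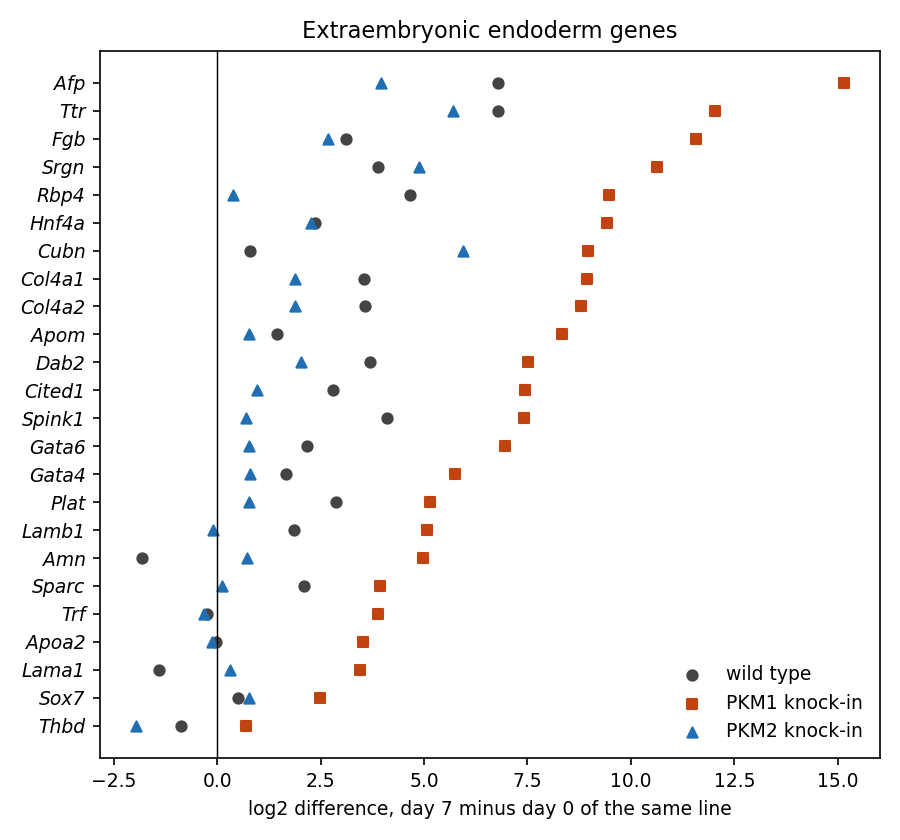
Log2 difference between day 7 and day 0 (horizontal axis) of the 24 extraembryonic endoderm genes (vertical axis), with a marker for each line, 1 array per line and day. Medians are 7.43 (PKM1 knock-in), 2.27 (wild type) and 0.77 (PKM2 knock-in).

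Within each line the changes from day 0 were also compared array against array. At day 3 the wild type array was highest for Myo1f (5.83), Wnk4 (4.75), Reg2 (4.30), Actn3 (4.27) and Lefty1 (4.14), the PKM1 knock-in array for Speer4d (4.86), Aass (4.35), Myo1f (4.29), Lefty1 (4.06) and Irx4 (4.04), and the PKM2 knock-in array for Lef1 (5.07), Duxbl2 (4.53), Vrtn (4.19), Aass (4.17) and Wt1 (3.80). The lowest were Fos (-9.12), Fosb (-7.74), Dcn (-7.60), Lcn2 (-6.72) and Egr1 (-6.57) in wild type. They were Dcn (-8.65), Fos (-8.00), Lcn2 (-7.38), Ifi27 (-7.13) and Atf3 (-6.57) in the PKM1 knock-in line, and Fos (-5.14), Ddx3y (-5.06), Acta2 (-4.94), Ifi27 (-4.91) and Ccl7 (-4.62) in the PKM2 knock-in line. At day 7 the highest were Acta2 (6.39), Amot (6.08), Prss12 (5.88), the retinoic acid hydroxylase gene Cyp26a1 (5.88) and Sfrp5 (5.66) in wild type. They were Aqp8 (10.53), Rbp4 (9.46), Cubn (8.96), Col4a1 (8.95) and Col4a2 (8.79) in the PKM1 knock-in line, and Cubn (5.95), Srgn (4.89), Itgb2 (4.87), Duxbl2 (4.12) and Apobec2 (3.99) in the PKM2 knock-in line. The lowest at day 7 were Fosb (-7.70), Mgp (-7.34), Egr2 (-7.07), Lcn2 (-6.92) and Fos (-6.84) in wild type. They were Lcn2 (-7.23), Dcn (-6.42), Fosb (-5.85), Cxcl5 (-5.81) and Fos (-5.79) in the PKM1 knock-in line, and Fos (-5.49), Tmem176b (-4.78), Ifi27 (-4.69), Slc11a1 (-4.59) and Anxa1 (-4.46) in the PKM2 knock-in line. Between 17 and 23 of the 40 lists lay outside the central 95 percent of random lists in these 6 comparisons.

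The sex chromosome genes were read on every array. Xist and the Y-linked Kdm5d were not well above background on any array. Eif2s3y read 6.34, 5.76 and 4.36 at days 0, 3 and 7 in wild type. It read 8.14, 8.33 and 9.16 in PKM1 knock-in, and 11.76, 7.66 and 4.36 in PKM2 knock-in, the last not well above background. Ddx3y was well above background on 4 arrays, at 5.37 (wild type day 0), 5.34 (PKM1 knock-in day 7), 9.80 and 4.74 (PKM2 knock-in days 0 and 3), and Uty on 2, at 5.38 and 6.83 (PKM2 knock-in days 0 and 3). Against wild type Eif2s3y differed by 3.06 ± 1.37 in the PKM1 knock-in line (adjusted p = 0.447, 2.94 with the slide as a block) and by 2.44 ± 1.37 in the PKM2 knock-in line (adjusted p = 0.498, 4.22 with the block, 5.41 within slide 1), and Ddx3y by 1.13 (adjusted p = 0.799) and 2.31 ± 1.27 (adjusted p = 0.486, 3.96 with the block, 4.43 within slide 1). Ftx, a noncoding gene of the X inactivation centre, differed by 0.62 (adjusted p = 0.488) and 0.56 (adjusted p = 0.482).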

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

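The tests of slide, scaling, probe, mislabelling and feeder cells below were chosen after seeing the results, while those of regrouped arrays and of exchanged day 7 arrays were fixed before.

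Fibroblast and feeder genes were lower at day 3 than at day 0. Slide was excluded by the median of -2.08 within slide 1, and scaling between arrays by -1.81 with quantile normalization. Whether feeder or other fibroblasts in the day 0 cultures explain the fall was left undecided. Of members well above background on all day 0 arrays, 88.2 percent (15 of 17) were lower in all 3 lines. This restates the fall, which any cause would give. The written bound of 90 percent was not met. A first run had a lower bound, which would have been met, and was corrected.

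Mest and Nudt12 were higher in both knock-in lines than in wild type. For Mest, slide was excluded by a difference of 7.02 within slide 1, and a probe reading another transcript by probes that differed by at least 3.84. For Nudt12, whose probe was not tested, the day 0 arrays of slide 1 alone, at least 1.86 apart, had left slide undecided, and a later test over all arrays of slides 1 and 2 excluded it, with each knock-in line at least 2.36 above wild type within a slide. Fits without 1 array gave changes of at least 2.33 for both, which excluded 1 mislabelled array. Genotype and the separate history of the lines could both give these values, and 1 line per genotype cannot tell them apart.

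Extraembryonic endoderm genes were higher at day 7 in the PKM1 knock-in line than in wild type. Slide was excluded, since the change within slide 2 exceeded that within slide 1 by 4.79. An exchange of the 2 knock-in arrays of day 7 was left undecided, with 38.5 percent (5 of 13) of line-specific genes keeping their sign against 49.5 percent of other genes. Between PKM1 and PKM2 knock-in, Meg3 kept its order of days 0 and 3 at day 7 (13.74 against 8.35). Eif2s3y had turned from its order of day 0 (8.14 against 11.76) by day 3 (8.33 against 7.66). It kept the order of day 3 at day 7 (9.16 against 4.36). The change in the PKM2 knock-in line was smaller than in wild type by a median of -1.09, and its day 7 array was alone on slide 3, so slide was not excluded there.

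Some lists moved in opposite directions between lines from day 0 to day 7, and these differences were not tested. Given are lists with medians beyond 0.5 in size and outside the central 95 percent of random lists both ways. Primitive streak medians were 1.82 in PKM1 knock-in and -1.16 in PKM2 knock-in, a difference of 2.98. Trophoblast medians were 1.48 and -1.30 in the same lines, a difference of 2.78. Hypoxia medians were 1.42 and -0.53, a difference of 1.95. Macrophage and leukocyte medians were 0.56 in PKM2 knock-in and -0.52 in wild type, a difference of 1.08 (0.66 in PKM1 knock-in, inside the central 95 percent).

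Arrays were also regrouped across the real groups. Pairwise contrasts allow only 10 splits, too few to judge. The real gene counts of 615, 14 and 0 between days stood beside highest other counts of 0, 0 and 1, and those of 2, 2 and 0 between genotypes beside 0, 1 and 0. Counting the real split, 1, 1, 10, 1, 1 and 10 splits reached the real count. For lists the real counts 16, 10, 17, 5, 11 and 8 were reached by 3, 6, 3, 10, 7 and 7 splits, with highest other counts of 22, 21, 23, 24, 26 and 21. For PKM1 knock-in against wild type the split calling 24 lists set both day 7 against both day 3 arrays. It holds a day difference, so whether camera calls too many lists is undecided. The split by slide called 7 and the slide block 3. For the F test over days 1 of 36 splits reached 179 (highest other 12), which excluded chance there. Over genotypes the 4 of 36 that reached 2 kept wild type apart from both knock-in lines, so they cannot judge chance. The rest gave 0.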

How the results depend on the processing

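All alternatives but the fits without 1 array were chosen before the data were examined, and the cause of a change was not tested. No paired analysis was possible because each line and day had 1 array, beyond the pairing of days within lines and of genotypes within days that the model already holds.

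Of 522 gene values (87 called), 14431 comparisons gave 12877 the same, 914 weaker, 549 stronger and 0 reversed, with 91 uncalled values turning sign. Of 67 list shifts, 1941 comparisons gave 1642 the same, 292 weaker and 7 reversed.

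At day 3 against day 0 the 615 genes became 929 with normexp (60.3 percent higher against 45.9), 150 with no filter, 1011 with trend and robust, 4218 with array weights, 1427 with only the 6 arrays compared and 1749 at adjusted p under 0.1, and leave-one-out gave 0 to 1257. At day 7 against day 0 the 14 became 5 with quantile normalization, 4 with no filter, 1 with genes well above background on all 9 arrays, 23 with trend and robust, 1778 with array weights, 9 with no block, 0 with only the 6 arrays compared and 57 at adjusted p under 0.1 (leave-one-out 0 to 225). Its 10 lists became 18 with the slide as a block (leave-one-out 9 to 20).

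At day 7 against day 3 the count of 0 became 35 with normexp, 71 with the filter on all 9 arrays, 1 with a floor of 20, 260 with trend and robust, 3932 with array weights, 6 with no block, 984 with the slide as a block and 1945 at adjusted p under 0.1 (leave-one-out 0 to 2393). Over days the F test count of 179 became 569 with normexp, 3 with no filter, 423 with the filter on all 9 arrays, 682 with trend and robust, 5506 with array weights, 724 with the slide as a block and 1592 at adjusted p under 0.1 (leave-one-out 0 to 2009).

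For PKM1 knock-in against wild type the 2 genes became 5 with normexp, 1 each with no filter, the filter on all 9 arrays, a floor of 1, a floor of 20 and the slide as a block, 340 with array weights, 0 with only the 6 arrays compared and 8 at adjusted p under 0.1. The 5 lists became 9 with normexp, 15 with array weights, 10 with only the 6 arrays compared, 3 with the slide as a block and 15 at adjusted p under 0.1 (leave-one-out 3 to 16). For PKM2 knock-in against wild type the 2 genes became 17 with normexp, 1 each with no filter, the filter on all 9 arrays and both floors, 6 with array weights, 0 with only the 6 arrays compared or the slide as a block and 7 at adjusted p under 0.1. The 11 lists became 7 with quantile normalization, 6 with the slide as a block and 18 at adjusted p under 0.1 (leave-one-out 0 to 18). Between the knock-in lines the 8 lists became 3 with array weights and 5 with the slide as a block (leave-one-out 4 to 13). Over genotypes the F test count of 2 became 1 with no filter, the filter on all 9 arrays, both floors, trend and robust and the slide as a block, and 64 with array weights. Leave-one-out gave 0 to 2 for these 3 gene counts.

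Camera with an estimated correlation called 0 lists in every contrast, and fry 7, 1, 0, 0, 0 and 0.

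Directions turned for extraembryonic endoderm in PKM1 knock-in against wild type (-0.29 without day 7, -0.34 without the PKM1 knock-in day 7 array) and for oxidative phosphorylation in PKM2 knock-in against wild type (-0.016 without the PKM2 knock-in day 7 array). Between the knock-in lines they turned for extraembryonic endoderm (0.11 with the slide as a block) and, without day 7, for ribosome biogenesis (-0.082), extraembryonic endoderm (-0.081) and definitive endoderm (-0.13), where for both endoderm lists only the test statistic turned. Medians alone also turned for oxidative phosphorylation in PKM2 knock-in against wild type (-0.020 with quantile normalization) and, between the knock-in lines, for definitive endoderm (0.091 with the slide as a block) and ribosome biogenesis (-0.064 with array weights, -0.033 without the PKM2 knock-in day 7 array). The leave-one-out ranges of these lists were -0.34 to 2.14 (without the PKM1 knock-in day 0 array) for extraembryonic endoderm in PKM1 knock-in against wild type, and -0.016 to 0.25 (without day 3) for oxidative phosphorylation. Between the knock-in lines they were -2.74 (without day 0) to -0.049 (without the PKM1 knock-in day 7 array) for extraembryonic endoderm, -1.87 (without day 0) to 0.022 (without the PKM2 knock-in day 7 array) for definitive endoderm, and -0.082 to 0.45 (without the PKM2 knock-in day 3 array) for ribosome biogenesis. In the single-array comparison of PKM1 knock-in with wild type at day 0, normexp turned mesoderm to 0.094, cardiac muscle to 0.060 and trophoblast to 0.14.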

Other observations

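The tests in this part were not planned, and its values were read after seeing the results. Smooth muscle actin Acta2 read 13.46 and 13.62 at day 7 in wild type and PKM1 knock-in and 4.28 in PKM2 knock-in, while Afp read 9.10, 17.73 and 6.29. Fos read 14.92, 14.20 and 11.45 at day 0 in wild type, PKM1 and PKM2 knock-in, and 5.80, 6.20 and 6.31 at day 3.

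The term for slide 2 against slide 1 called 0 genes in limma (514 at an unadjusted p under 0.05).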
